A study of Mus musculus with 24 samples.

How the data were processed

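RNA of 24 libraries was sequenced from 2 mouse cell lines at the end of a migration assay between culture-insert chambers: K-Luc, a luciferase-expressing KR158B glioma line, and RAW-Blue, RAW macrophages with a reporter for NF-kB and AP-1. Each line has 5 groups, untreated (water), CpG-28 oligonucleotide, single-walled carbon nanotubes in lipid-PEG (SWNT/LP), CpG and SWNT/LP together, and nanotubes dispersed in CpG-28 (SWNT/CpG), each ingredient at 10 µg/mL. Treatment lasted 17 to 19 h for K-Luc and 47 to 50 h for RAW-Blue, after 24 h of adhesion. K-Luc has 2 untreated libraries and 3 in each other group, and RAW-Blue 2 in every group. The labels name 2 runs: 3 K-Luc libraries (1 untreated, 1 CpG+SWNT/LP and 1 SWNT/CpG) are run 1, and all others run 2. No group received an oligonucleotide without CpG, so effects of the CpG motif and of DNA as such are not separated. The labels do not say whether replicates are separate cultures, so the p-values measure a spread between samples that may be technical. Migration itself was not analysed here.

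Libraries were made from poly(A) RNA with a stranded kit. Per the submitters' processing notes the authors used TopHat2 2.0.14, HTSeq 0.6.0 and the mm9 build, and the annotation, strand setting and filters are not given in the sources used here. The deposited table of read counts holds raw counts for 21669 genes, and all 24 of its libraries were matched to the labels. A deposited table in RPKM, rounded by the authors, was used only to check the counts: over 1370 genes at RPKM above 20 in every library, library sizes implied by the 2 tables had ratios of 0.975 to 1.139. Totals run from 13.3 to 24.1 M counts per library. A gene at 1 CPM thus has 13 counts in the smallest library and 24 in the largest, a counting error of 27.4% and 20.4%, which leaves out all spread between samples.

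Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total 15), robust dispersion, and the quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, called at an adjusted p under 0.05. All groups of a line share 1 fit. The K-Luc fit has group and run terms (14 libraries, 8 residual degrees of freedom, 12420 genes), the RAW-Blue fit has group alone (10 libraries, 5 residual degrees of freedom, 11514 genes), and a fit of both lines has group and run (13 residual degrees of freedom, 13350 genes). The biological coefficient of variation was 0.051 in K-Luc and 0.086 in RAW-Blue. The K-Luc run term was called for 2155 genes. All run 1 libraries are replicate 1, so this term does not tell run from a difference of replicate 1. Replicate 1 of CpG and of SWNT/LP is run 2, so the term does not remove such a difference there. Standard errors of log2 fold changes come from the fold change and its F statistic.

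Before the data were examined, 17 comparisons were fixed. Each line has 8: each of the 4 treatments against untreated, SWNT/CpG against each of the 3 other treatments, and the interaction of CpG and SWNT/LP. The last tests whether the response to SWNT/CpG differs between the lines. CpG+SWNT/LP against CpG, and the SWNT/LP effect averaged over CpG in K-Luc, were added after the data were seen. Fixed at the same time were 25 gene lists, of which 24 are reported: cytokines, NF-kB feedback, interferon response, nucleic acid sensors and TLR signalling, antigen presentation, NRF2 antioxidant genes, heat shock and metal response, unfolded protein and ATF4 response, lysosome, autophagy, cholesterol synthesis, lipid efflux and storage, focal adhesion and integrins, extracellular matrix and proteases, SRF and YAP targets, mesenchymal and TGF-beta genes, cell cycle, p53 targets and apoptosis, glycolysis and hypoxia, phagocytic and scavenger receptors, the osteoclast programme, and markers of macrophages, glia, and fibroblasts and vessels. They were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, and again with the correlation estimated and with fry. In comparisons of 2 groups, members with 3 or fewer counts in a group were also set to a floor of 3 counts. This moved no list median by more than 0.04 among lists of over 4 members. The interactions and the comparison between the lines had no such check.

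Genes are named by a rule fixed with the comparisons: the 10 largest rises and 10 largest falls (5 and 5 in most comparisons) among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the 2 groups, up to 4 members of each list with the smallest adjusted p, and Tlr9, Unc93b1, Myd88, Actb, Gapdh and Tnf as values. Genes with 3 or fewer counts in a compared group are not named. Gapdh, with 2.88 CPM in K-Luc and 7.7 in RAW-Blue, is not interpreted. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, replicate number as a block, only the compared groups in the fit, no run term, run 2 alone, and each library left out in turn. Removal of a GC content trend in RAW-Blue was added after the data were seen, with GC content taken by gene symbol from a reference of another build, which matched 97.2% of tested genes. The pipeline was tested on simulated data with known changes. Each simulation changed 67 genes by 1.5-fold, 67 by 2-fold and 66 by 4-fold in 1 group. It held no run, replicate or GC content effect, and with fewer true changes a smaller share may be called. Of genes changed by 1.5-fold the pipeline called 74.6% for K-Luc SWNT/CpG against untreated, 53.7% for RAW-Blue and 49.3% between the lines. Of those changed by 2-fold it called 85.1%, 86.6% and 77.6%. In the same order, 8 of 181 calls, 23 of 180 and 7 of 150 were false. For the interaction of CpG and SWNT/LP, 10 of 176 calls were false in K-Luc and 9 of 118 in RAW-Blue. The share was highest for RAW-Blue SWNT/CpG against untreated, above the level the adjusted p is set to allow. Calls in RAW-Blue may thus hold more false ones than their adjusted p states.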

Results

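**Figure D1:**
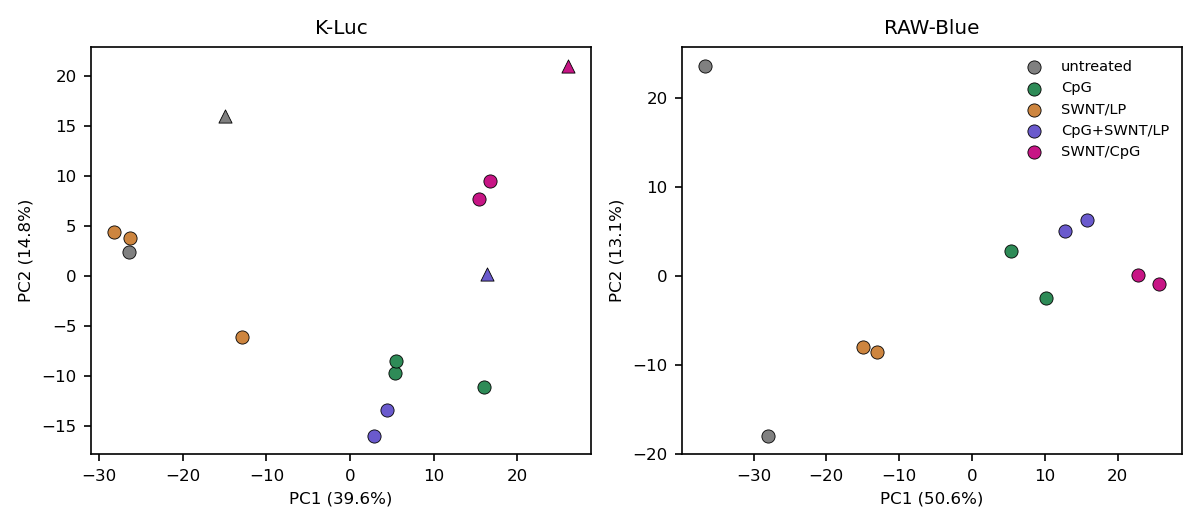
Principal components of log2 CPM over the tested genes of each cell line. Triangles are run 1 libraries and circles run 2 libraries.

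The 24 libraries cover 2 mouse cell lines, K-Luc glioma cells and RAW-Blue macrophages. Each was left in water or given a CpG oligonucleotide (CpG), nanotubes in lipid-PEG (SWNT/LP), those 2 together (CpG+SWNT/LP), or nanotubes coated with the oligonucleotide itself (SWNT/CpG). In K-Luc cells the 1st principal component (39.6% of variance) has the untreated and SWNT/LP libraries on one side. All libraries that received the oligonucleotide lie on the other. In RAW-Blue cells it holds 50.6% of variance and runs from untreated through SWNT/LP, CpG and CpG+SWNT/LP to SWNT/CpG. Values in brackets after a gene are its log2 fold change ± standard error, and levels are CPM, mean ± SD. Values after a list are the median log2 fold change of its members and the adjusted p of camera. The number of members passing is given again, adjusted over the list alone, where that differs.

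**Figure D2:**
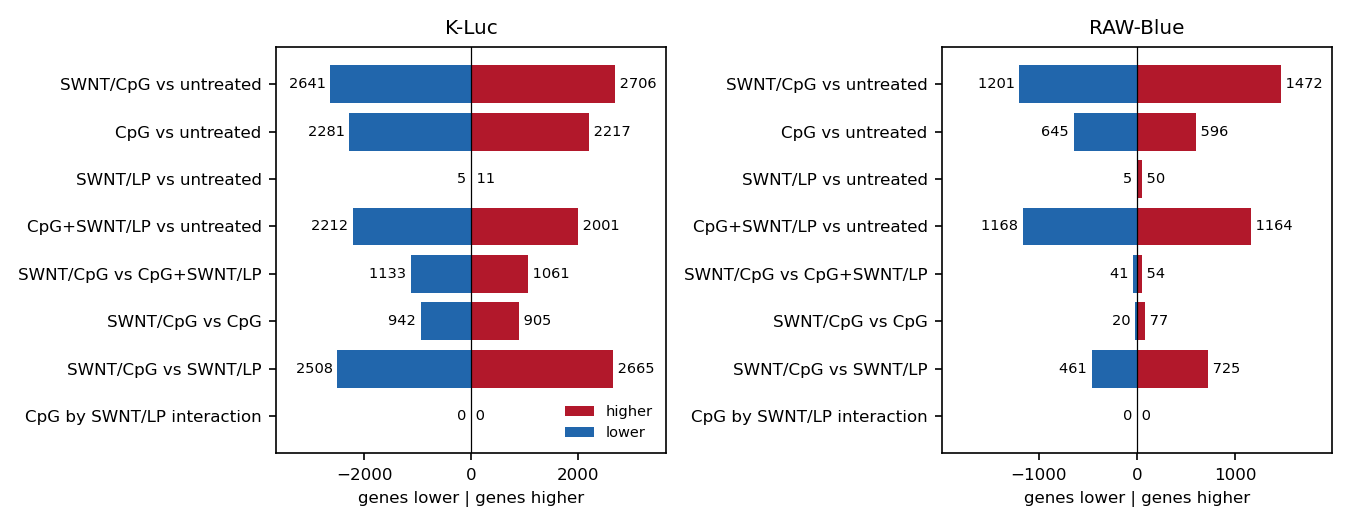
Genes higher and lower in each planned comparison within a cell line, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

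All 35 fixed cell cycle genes fell in K-Luc cells given SWNT/CpG (n = 3) rather than water (n = 2). Their median was -0.95 (adjusted p = 4.4e-67, adjusted p = 0.0308 with an estimated correlation). Among them were Cdc20 (-1.02 ± 0.05, adjusted p = 4.37e-10), which starts anaphase, the kinetochore genes Cenpf (-1.01 ± 0.05) and Cenpe (-0.95 ± 0.05), and the mitotic kinase Aurkb (-1.04 ± 0.05). Among the largest rises were Anxa8 (16.5 ± 2.1 against 2.74 ± 1.4 CPM, log2 fold change 2.75 ± 0.21, adjusted p = 7.14e-08), a phospholipid-binding annexin, and the complement gene C3 (95.8 ± 16 against 18.0 ± 7.3 CPM, log2 fold change 2.32 ± 0.23, adjusted p = 2.58e-05). The intermediate filament gene Synm (2.26 ± 0.22) and the collagen-binding integrin genes Itga2 (2.20 ± 0.24) and Itga11 (2.17 ± 0.35) also rose. The largest falls were in the aldehyde dehydrogenase Aldh3a1 (8.36 ± 0.88 against 32.2 ± 10 CPM, log2 fold change -2.04 ± 0.29, adjusted p = 0.000281) and in Id2 (18.2 ± 0.61 against 61.2 ± 16 CPM, log2 fold change -1.79 ± 0.19, adjusted p = 1.67e-05). Id1 (-1.46 ± 0.14), whose protein like Id2 blocks basic helix-loop-helix factors, the junction gene Ppl (-1.48 ± 0.11) and the cytochrome P450 gene Cyp1b1 (-1.37 ± 0.24) fell as well.

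Smooth muscle actin Acta2 (1.20 ± 0.07, adjusted p = 5.45e-09) and the myosin light chain Myl9 (1.25 ± 0.09) rose. They belong to the SRF and YAP targets, of which 16 of 30 rose and 4 fell. Their median was 0.28 (adjusted p = 0.00102, adjusted p = 0.284 with an estimated correlation, 16 higher and 5 lower adjusted over the list alone). Of the matrix genes 26 of 36 rose and 4 fell, with Thbs1 (1.04 ± 0.07), Col5a2 (0.74 ± 0.05), Sparc (0.71 ± 0.06) and Col1a2 (0.60 ± 0.05) at the smallest p. Their median was 0.50 (adjusted p = 1.13e-08, adjusted p = 0.196 with an estimated correlation, 26 higher and 5 lower adjusted over the list alone). The matrix gene Postn (440 ± 172 against 106 ± 56 CPM, log2 fold change 2.26 ± 0.48, adjusted p = 0.00561) and the collagen-binding Fmod (2.04 ± 0.45) were among the largest rises of all genes. Of the focal adhesion and integrin genes 21 of 31 rose and 2 fell, the laminin-binding subunit Itga6 (-0.88 ± 0.09) among the falls. Their median was 0.20 (adjusted p = 5.51e-05, adjusted p = 0.284 with an estimated correlation, 22 higher and 2 lower adjusted over the list alone).

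Of the lysosomal genes 29 of 34 rose, among them the membrane gene Lamp2 (0.40 ± 0.05). Their median was 0.38 (adjusted p = 7.33e-08, adjusted p = 0.394 with an estimated correlation, 30 higher and 0 lower adjusted over the list alone). Of the autophagy genes 13 of 20 rose, led by Wipi1 (0.67 ± 0.07) and Map1lc3b (0.58 ± 0.06). Their median was 0.25 (adjusted p = 0.000133, adjusted p = 0.243 with an estimated correlation). Of the NF-kB feedback genes 12 of 21 rose and 1 fell, with the inhibitor Nfkbie (0.84 ± 0.10) and the RNase Zc3h12a (0.79 ± 0.08) higher. Their median was 0.31 (adjusted p = 0.000557, adjusted p = 0.196 with an estimated correlation). Of the antigen presentation genes 10 of 17 rose, with Tapbp (0.88 ± 0.08) and H2-K1 (0.55 ± 0.07). Their median was 0.32 (adjusted p = 0.000492, adjusted p = 0.196 with an estimated correlation, 11 higher and 0 lower adjusted over the list alone). Of the sensor and TLR signalling genes 10 of 22 rose and 2 fell, with Tlr2 (1.59 ± 0.09, adjusted p = 1.37e-09) highest. Their median was 0.24 (adjusted p = 0.0473, adjusted p = 0.196 with an estimated correlation, 11 higher and 2 lower adjusted over the list alone). Of the cholesterol synthesis genes 12 of 24 rose and 1 fell, with Hsd17b7 (0.62 ± 0.07) and Ebp (0.54 ± 0.05) higher. Their median was 0.13 (adjusted p = 0.0178, adjusted p = 0.54 with an estimated correlation). Of the NRF2 antioxidant genes 3 of 26 rose and 15 fell, the quinone reductase Nqo1 (-0.81 ± 0.09) among the falls. Their median was -0.19 (adjusted p = 0.0131, adjusted p = 0.284 with an estimated correlation, 3 higher and 16 lower adjusted over the list alone).

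Camera called none of the other lists given here. Cytokines had 6 higher and 3 lower of 14, 7 and 3 adjusted over the list alone, adjusted p = 0.314. The interferon response had 10 higher and 7 lower of 40, adjusted p = 0.273, heat shock and metal response 3 higher and 10 lower of 18, 3 and 11 adjusted over the list alone, adjusted p = 0.299, and the unfolded protein and ATF4 response 11 higher and 7 lower of 29, 12 and 7 adjusted over the list alone, adjusted p = 0.314. Lipid efflux and storage had 3 higher and 3 lower of 22, 2 and 3 adjusted over the list alone, adjusted p = 0.905. Mesenchymal genes had 12 higher and 8 lower of 30, 12 and 9 adjusted over the list alone, adjusted p = 0.648, p53 targets 10 higher and 3 lower of 25, adjusted p = 0.0733, and glycolysis 6 higher and 6 lower of 29, adjusted p = 0.502. Phagocytic receptors had 4 higher and 0 lower of 8, adjusted p = 0.0966, and the osteoclast programme 5 higher and 0 lower of 9, adjusted p = 0.0615. Macrophage markers had 1 higher and 0 lower of 4, adjusted p = 0.547, glial markers 1 higher and 2 lower of 12, adjusted p = 0.776, and fibroblast and vascular markers 1 higher and 0 lower of 8, adjusted p = 0.496. Single members passed, among them the death receptor Fas (1.70 ± 0.15), the iron exporter Slc40a1 (1.90 ± 0.16), the interferon-induced GTPase Ifi47 (1.05 ± 0.08) and the glial factor Sox2 (-0.50 ± 0.05). In all, edgeR called 2706 genes higher and 2641 lower of 12420 tested, 250 and 134 of them by over 2-fold. Without untreated replicate 2 the count was 2770.

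The oligonucleotide alone (n = 3, untreated n = 2) also lowered all 35 cell cycle genes in K-Luc cells, among them Cenpf (-0.57 ± 0.05) and Cdc20 (-0.54 ± 0.05). Their median was -0.58 (adjusted p = 4.35e-40, adjusted p = 0.132 with an estimated correlation). Its largest rises include the matrix proteoglycans Prelp (50.6 ± 18 against 11.2 ± 6.5 CPM, log2 fold change 2.66 ± 0.45, adjusted p = 0.0018) and Fmod (2.29 ± 0.47) and the smooth muscle gene Lmod1 (2.37 ± 0.33). Its largest falls include Il1rl1 (88.9 ± 28 against 230 ± 88 CPM, log2 fold change -1.74 ± 0.28, adjusted p = 0.00146), the interleukin-33 receptor, the acyl-CoA synthetase Acsbg1 (-1.55 ± 0.17), and the interleukin-18 receptor subunit Il18rap (-1.07 ± 0.12). Of the glycolysis and hypoxia genes 2 of 29 rose and 18 fell, with lactate dehydrogenase Ldha (-0.47 ± 0.05, adjusted p = 1.44e-05), Tpi1 (-0.40 ± 0.05) and Vegfa (-0.43 ± 0.05) lower. Their median was -0.31 (adjusted p = 5.44e-05, adjusted p = 0.371 with an estimated correlation).

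Of the lysosomal genes 25 of 34 rose. Their median was 0.36 (adjusted p = 3.48e-06, adjusted p = 0.515 with an estimated correlation, 27 higher and 1 lower adjusted over the list alone). Of the matrix genes 20 of 36 rose and 4 fell, with Col6a1 (0.68 ± 0.07) and Thbs1 (0.71 ± 0.08) higher. Their median was 0.34 (adjusted p = 5.44e-05, adjusted p = 0.461 with an estimated correlation, 23 higher and 5 lower adjusted over the list alone). Contractile Acta2 (0.88 ± 0.08) rose, and of the SRF and YAP targets 11 of 30 rose and 2 fell. Their median was 0.15 (adjusted p = 0.0106, adjusted p = 0.461 with an estimated correlation). In the mesenchymal list 10 of 30 rose and 5 fell, with Id3 (0.59 ± 0.07, adjusted p = 1.56e-05) and the ligand gene Bmp4 (0.65 ± 0.11) among the rises. Their median was 0.10 (adjusted p = 0.0341, adjusted p = 0.252 with an estimated correlation). Interferon response genes had 6 higher and 1 lower of 40, adjusted p = 0.121. Cytokines had 0 higher and 2 lower of 14, adjusted p = 0.408, with Ccl7 (-0.60 ± 0.15) and Lif (-0.50 ± 0.13) lower. By edgeR 2217 genes were higher and 2281 lower, 199 and 25 by over 2-fold. The count was 1531 without untreated replicate 2, and 2543 when only these 2 groups entered the fit.

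Nanotubes in lipid-PEG (n = 3, untreated n = 2) changed few genes in K-Luc cells. Of the 11 genes called higher, 7 belong to the fixed glycolysis and hypoxia list. They include the mitophagy gene Bnip3 (44.0 ± 1.7 against 29.4 ± 2.0 CPM, log2 fold change 0.69 ± 0.08, adjusted p = 0.00122) and Pdk1 (105 ± 9.9 against 71.5 ± 0.59 CPM, log2 fold change 0.60 ± 0.07, adjusted p = 0.00123), which restrains pyruvate dehydrogenase. The phosphofructokinase Pfkl (0.51 ± 0.07, adjusted p = 0.00241) and Ldha (0.34 ± 0.05) rose too. In the whole list 7 of 29 rose. Their median was 0.25 (adjusted p = 5.97e-53, adjusted p = 0.000718 with an estimated correlation, 18 higher and 0 lower adjusted over the list alone). The falls were in the uncharacterised 1190005I06Rik (-1.61 ± 0.14, adjusted p = 6.36e-05), the gasdermin gene Dfna5 (-0.81 ± 0.12), the quinone reductase Nqo1 (21.7 ± 1.5 against 31.7 ± 5.5 CPM, log2 fold change -0.66 ± 0.10, adjusted p = 0.00583), the alcohol dehydrogenase Adh7 (-0.44 ± 0.06) and Arl6ip5 (-0.42 ± 0.06). Of the NRF2 genes 1 of 26 fell. Their median was -0.08 (adjusted p = 9.3e-08, adjusted p = 0.0885 with an estimated correlation, 0 higher and 2 lower adjusted over the list alone).

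Cell cycle genes had 0 higher and 0 lower of 35, adjusted p = 0.0528. Camera called the lysosome list with no member passing. Their median was 0.11 (adjusted p = 2.62e-06, adjusted p = 0.523 with an estimated correlation). It also called the interferon response with no member passing. Their median was 0.13 (adjusted p = 1.44e-05, adjusted p = 0.523 with an estimated correlation). The edgeR test called 11 genes higher and 5 lower, with 538 genes at unadjusted p under 0.05. DESeq2 called 33, and edgeR 27 without a filter on low counts, 5 in run 2 alone (1 higher and 4 lower) and 2 with only these 2 groups in the fit (0 higher and 2 lower), so nearly all calls of a rise ended in these 2 settings. The count was 0 without untreated replicate 2 and 8 without untreated replicate 1.

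Given both components unjoined (n = 3, untreated n = 2), K-Luc cells had all 35 cell cycle genes lower, Cdc20 (-0.55 ± 0.04) among them. Their median was -0.50 (adjusted p = 7.65e-34, adjusted p = 0.199 with an estimated correlation). The proteoglycan Prelp (49.8 ± 14 against 11.2 ± 6.5 CPM, log2 fold change 2.35 ± 0.42, adjusted p = 0.0028), the lens crystallin gene Crygs (2.34 ± 0.38), the phosphodiesterase Gdpd2 (2.18 ± 0.27) and angiotensinogen Agt (2.10 ± 0.22, adjusted p = 9.37e-06) were among the largest rises. The interleukin-33 receptor Il1rl1 (-1.52 ± 0.27, adjusted p = 0.00244), Acsbg1 (-1.40 ± 0.16) and the integrin gene Itgb7 (-1.09 ± 0.18) fell most. Of the matrix genes 22 of 36 rose and 2 fell, with Col6a1 (0.62 ± 0.07) higher and the inhibitor Timp1 (-0.71 ± 0.09) lower. Their median was 0.36 (adjusted p = 2.54e-06, adjusted p = 0.435 with an estimated correlation, 24 higher and 3 lower adjusted over the list alone).

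Of the lysosomal genes 22 of 34 rose. Their median was 0.28 (adjusted p = 3.03e-05, adjusted p = 0.534 with an estimated correlation, 24 higher and 0 lower adjusted over the list alone). Among SRF and YAP targets 10 of 30 rose and 3 fell, with Acta2 (0.86 ± 0.07) higher. Their median was 0.17 (adjusted p = 0.00654, adjusted p = 0.435 with an estimated correlation). In the NRF2 list 1 of 26 rose and 12 fell. Their median was -0.09 (adjusted p = 0.00811, adjusted p = 0.435 with an estimated correlation, 2 higher and 12 lower adjusted over the list alone). Glycolysis genes had 3 higher and 7 lower of 29, adjusted p = 0.617. The chemokine Cxcl12 (0.74 ± 0.06) and Id3 (0.58 ± 0.06) rose, and the prostaglandin synthase Ptgs2 (-0.79 ± 0.14) fell. By edgeR 2001 genes were higher and 2212 lower, 148 and 21 by over 2-fold, and in run 2 alone 2043 changed. The count was 1454 without untreated replicate 2, 2685 without untreated replicate 1, and 2746 without CpG+SWNT/LP replicate 1.

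**Figure D3:**
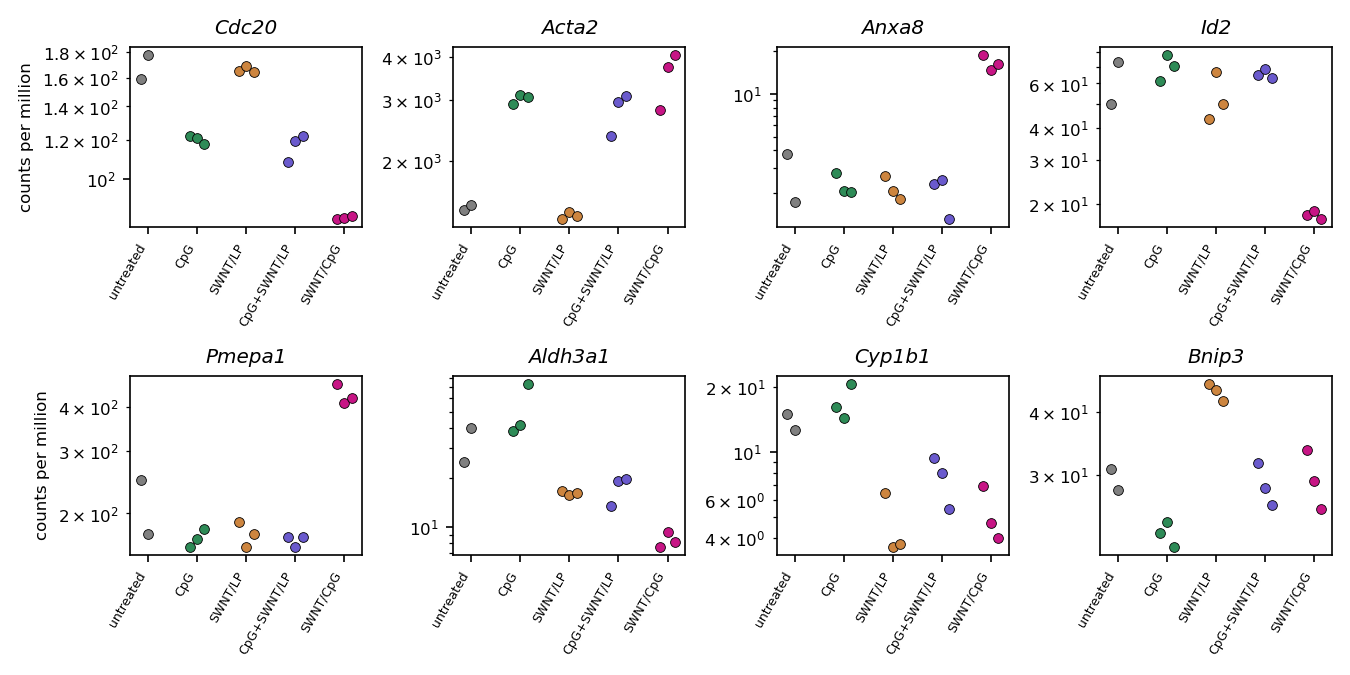
CPM of 8 named genes in each K-Luc library, log scale.

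SWNT/CpG against CpG+SWNT/LP (n = 3 each) keeps the nanotube and the oligonucleotide and changes how they are joined and whether lipid-PEG is present. In K-Luc cells it lowered Id2 (18.2 ± 0.61 against 65.4 ± 2.8 CPM, log2 fold change -1.86 ± 0.17, adjusted p = 2.12e-05), Id1 (24.3 ± 1.1 against 78.5 ± 12 CPM, log2 fold change -1.70 ± 0.12, adjusted p = 1.04e-06) and Id3 (-1.33 ± 0.06, adjusted p = 1.03e-09), and the helix-loop-helix gene Atoh8 (-1.22 ± 0.06, adjusted p = 3.62e-09). Higher were Pmepa1 (435 ± 29 against 168 ± 6.2 CPM, log2 fold change 1.37 ± 0.08, adjusted p = 4.47e-08), a target and inhibitor of TGF-beta signalling, and the growth factor Pdgfb (212 ± 17 against 84.2 ± 8.7 CPM, log2 fold change 1.34 ± 0.07, adjusted p = 3.62e-09). Anxa8 (3.02 ± 0.18, adjusted p = 2.64e-08), the metalloprotease Tll1 (2.37 ± 0.19), the cathepsin Ctsw (2.02 ± 0.12) and the chemokine receptor Cxcr6 (1.96 ± 0.21) rose too. Of the cell cycle genes 31 of 35 fell, Aurkb (-0.60 ± 0.05) and Plk1 (-0.59 ± 0.05) among them. Their median was -0.43 (adjusted p = 2.21e-42, adjusted p = 0.106 with an estimated correlation, 0 higher and 34 lower adjusted over the list alone). In the mesenchymal and TGF-beta list, which holds the Id genes, 7 of 30 rose and 11 fell, the SMAD corepressor Skil (0.60 ± 0.05) among the rises. Their median was -0.03 (adjusted p = 0.0455, adjusted p = 0.181 with an estimated correlation, 8 higher and 11 lower adjusted over the list alone).

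Of the NF-kB feedback genes 11 of 21 rose and 1 fell, with Nfkbie (0.65 ± 0.08) and Tnfaip3 (0.55 ± 0.09) among the rises. Their median was 0.29 (adjusted p = 3.24e-05, adjusted p = 0.106 with an estimated correlation). Of the unfolded protein and ATF4 genes 13 of 29 rose and 1 fell, with the stress factors Nupr1 (0.99 ± 0.06, adjusted p = 3.8e-08) and Xbp1 (0.45 ± 0.05) higher. Their median was 0.17 (adjusted p = 9.42e-07, adjusted p = 0.106 with an estimated correlation, 17 higher and 3 lower adjusted over the list alone). Of the cholesterol synthesis genes 12 of 24 rose, Ebp (0.46 ± 0.05) among them. Their median was 0.16 (adjusted p = 9.42e-07, adjusted p = 0.243 with an estimated correlation, 13 higher and 0 lower adjusted over the list alone). Of the antigen presentation genes 6 of 17 rose. Their median was 0.22 (adjusted p = 0.00619, adjusted p = 0.243 with an estimated correlation, 10 higher and 1 lower adjusted over the list alone). Cytokines had 5 higher and 2 lower of 14, adjusted p = 0.0552, with Lif (0.79 ± 0.11), Ccl9 (0.89 ± 0.17) and Ccl2 (0.67 ± 0.16) higher. By edgeR 1061 genes were higher and 1133 lower, 62 and 40 by over 2-fold. The count was 1423 without CpG+SWNT/LP replicate 1, 1177 in run 2 alone and 3695 with only these groups in the fit.

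With SWNT/CpG rather than the free oligonucleotide (n = 3 each), the chemokine genes Ccl7 (1.07 ± 0.13, adjusted p = 2.46e-05), Ccl2 (1.14 ± 0.17, adjusted p = 0.000514) and Ccl9 (0.89 ± 0.17) and the interleukin-6 family gene Lif (0.81 ± 0.11) rose in K-Luc cells. Of the cytokine genes 6 of 14 rose. Their median was 0.59 (adjusted p = 0.000262, adjusted p = 0.0366 with an estimated correlation, 7 higher and 1 lower adjusted over the list alone). Among NF-kB feedback genes 12 of 21 rose, Zc3h12a (0.68 ± 0.07) and Tnfaip3 (0.80 ± 0.10) among them. Their median was 0.29 (adjusted p = 1.13e-09, adjusted p = 0.0366 with an estimated correlation, 14 higher and 0 lower adjusted over the list alone). The xenobiotic genes Aldh3a1 (8.36 ± 0.88 against 51.2 ± 20 CPM, log2 fold change -2.48 ± 0.26, adjusted p = 0.000136) and Cyp1b1 (5.20 ± 1.6 against 17.1 ± 3.2 CPM, log2 fold change -1.90 ± 0.21, adjusted p = 4.1e-05) fell most, then Id2 (-1.89 ± 0.17), 1190005I06Rik (-1.66 ± 0.12) and the transporter Slc16a11 (-1.63 ± 0.22). Anxa8 (2.70 ± 0.18, adjusted p = 1.05e-07), Ctsw (2.05 ± 0.13), Cxcr6 (2.00 ± 0.22), Tll1 (1.70 ± 0.18) and Pdgfb (1.48 ± 0.07, adjusted p = 1.79e-09) rose most.

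Of the cell cycle genes 26 of 35 fell. Their median was -0.34 (adjusted p = 2.62e-26, adjusted p = 0.083 with an estimated correlation, 0 higher and 30 lower adjusted over the list alone). Of the cholesterol synthesis genes 14 of 24 rose, with Ebp (0.50 ± 0.05). Their median was 0.21 (adjusted p = 1.9e-10, adjusted p = 0.137 with an estimated correlation). Of the unfolded protein and ATF4 genes 12 of 29 rose, with Nupr1 (0.99 ± 0.07). Their median was 0.16 (adjusted p = 9.81e-08, adjusted p = 0.0673 with an estimated correlation, 16 higher and 1 lower adjusted over the list alone). Among glycolysis and hypoxia genes 12 of 29 rose and 1 fell, with Vegfa (0.66 ± 0.05) higher. Their median was 0.21 (adjusted p = 1.54e-06, adjusted p = 0.104 with an estimated correlation, 14 higher and 1 lower adjusted over the list alone). In the NRF2 list 1 of 26 rose and 7 fell, with Nqo1 (-0.77 ± 0.09) lower. Their median was -0.06 (adjusted p = 0.000812, adjusted p = 0.137 with an estimated correlation, 2 higher and 10 lower adjusted over the list alone). By edgeR 905 genes were higher and 942 lower, 65 and 44 by over 2-fold. The count was 1091 without SWNT/CpG replicate 2 and 1155 without SWNT/CpG replicate 3.

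With nanotubes in both arms and the coating changed from lipid-PEG to the oligonucleotide (n = 3 each), all 35 cell cycle genes of K-Luc cells fell, Plk1 (-1.09 ± 0.05) and Cenpf (-1.03 ± 0.04) among them. Their median was -0.90 (adjusted p = 5.17e-67, adjusted p = 0.0318 with an estimated correlation). Contractile Acta2 (1.44 ± 0.06) and Myl9 (1.42 ± 0.08), the integrin genes Itga2 (2.47 ± 0.22) and Itga11 (2.46 ± 0.33), and Anxa8 (2.80 ± 0.19) rose. Among glycolysis and hypoxia genes 1 of 29 rose and 20 fell, with Ldha (-0.75 ± 0.05, adjusted p = 5.1e-09), Tpi1 (-0.63 ± 0.05) and the oxygen-sensing hydroxylase Egln3 (-1.22 ± 0.08) lower. Their median was -0.39 (adjusted p = 8.92e-08, adjusted p = 0.167 with an estimated correlation). The lactate exporter Slc16a3 (-1.40 ± 0.20), the phosphate regulator Phex (-1.53 ± 0.25), Id2 (-1.51 ± 0.18) and Nlrp2 (-1.46 ± 0.19) were among the largest falls.

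Of the matrix genes 27 of 36 rose and 5 fell. Their median was 0.44 (adjusted p = 3.5e-09, adjusted p = 0.167 with an estimated correlation). Among SRF and YAP targets 17 of 30 rose and 5 fell. Their median was 0.32 (adjusted p = 1.35e-05, adjusted p = 0.201 with an estimated correlation, 18 higher and 5 lower adjusted over the list alone). Among NF-kB feedback genes 14 of 21 rose and 1 fell. Their median was 0.23 (adjusted p = 0.00085, adjusted p = 0.167 with an estimated correlation). By edgeR 2665 genes were higher and 2508 lower, 209 and 115 by over 2-fold.

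Whether the log2 fold changes of CpG and SWNT/LP add up in K-Luc cells was tested (n = 3, 3, 3 and 2). The test took the difference between the SWNT/LP log2 fold change with and without CpG. Sums of levels in CPM were not tested. No gene differed by edgeR (427 of 12420 at unadjusted p under 0.05, smallest adjusted p = 0.937), and DESeq2 also called 0. Camera called the cell cycle list with no member passing. Their median was 0.15 (adjusted p = 1.28e-09, adjusted p = 0.664 with an estimated correlation). The lysosome list was called in the same way. Their median was -0.17 (adjusted p = 4.48e-08, adjusted p = 0.664 with an estimated correlation). In simulated data with these group sizes 85.1% of genes changed by 2-fold and 67.2% of those changed by 1.5-fold were called, so smaller departures can be missed. The simulation changed many genes at once, so isolated departures may be missed more often.

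CpG+SWNT/LP against CpG in K-Luc cells (n = 3 each) was added after the data were seen. Of the glycolysis and hypoxia genes 4 of 29 rose, with Pdk1 (0.39 ± 0.06, adjusted p = 0.0114), Pfkl (0.36 ± 0.06) and Ldha (0.29 ± 0.05). Their median was 0.22 (adjusted p = 2e-31, adjusted p = 0.00472 with an estimated correlation, 20 higher and 0 lower adjusted over the list alone). The xenobiotic genes Aldh3a1 (-1.42 ± 0.23, adjusted p = 0.046) and Cyp1b1 (-1.34 ± 0.20, adjusted p = 0.0114) and the uncharacterised 1190005I06Rik (-1.54 ± 0.12, adjusted p = 5.02e-06) were lower, as was the pentraxin Ptx3 (-0.91 ± 0.15). Of the NRF2 genes 2 of 26 fell. Their median was -0.08 (adjusted p = 7.65e-08, adjusted p = 0.0542 with an estimated correlation, 0 higher and 5 lower adjusted over the list alone). By edgeR 7 genes were higher and 26 lower, and between 4 and 30 in all changed when 1 library was left out. The count was 5 in run 2 alone, 10 with only these groups in the fit, 15 without a run term and 47 by DESeq2.

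In RAW-Blue macrophages given SWNT/CpG (n = 2) rather than water (n = 2), 23 of 25 cytokine genes rose. Their median was 2.22 (adjusted p = 2.16e-64, adjusted p = 0.0755 with an estimated correlation). Inducible nitric oxide synthase Nos2 (151 ± 9.4 against 3.83 ± 0.17 CPM, log2 fold change 5.29 ± 0.19, adjusted p = 7.56e-07), the chemokine Ccl2 (3.88 ± 0.14) and Tnf (2.22 ± 0.08, adjusted p = 6.53e-07) were among them. The chemokine Cxcl2 (378 ± 105 against 14.3 ± 3.4 CPM, log2 fold change 4.72 ± 0.23, adjusted p = 6.21e-06), also in the list, rose too. Larger still were the rises of the iron-binding Lcn2 (64.5 ± 29 against 0.193 ± 0.050 CPM, log2 fold change 8.34 ± 0.65, adjusted p = 5.82e-05), from 7 counts untreated, and the granulocyte growth factor Csf3 (77.4 ± 19 against 0.412 ± 0.062 CPM, log2 fold change 7.53 ± 0.34, adjusted p = 3.9e-06). Of the interferon response genes 38 of 43 rose, with Isg15 (2.26 ± 0.18, adjusted p = 3.01e-05), the nucleotide kinase Cmpk2 (2.19 ± 0.21) and Trim30a (1.5 ± 0.14). Their median was 1.5 (adjusted p = 1.02e-27, adjusted p = 0.436 with an estimated correlation, 41 higher and 1 lower adjusted over the list alone). The sialyltransferase St6gal1 (4.01 ± 0.79 against 33.9 ± 2.0 CPM, log2 fold change -3.09 ± 0.13, adjusted p = 1.18e-06), the adhesion regulator Cytip (-3.04 ± 0.16), Pmepa1 (-2.77 ± 0.28, adjusted p = 0.000139) and the chemokine receptor Cxcr4 (4.11 ± 1.1 against 23 ± 0.78 CPM, log2 fold change -2.50 ± 0.18, adjusted p = 1.8e-05) were among the largest falls.

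Among NF-kB feedback genes 11 of 24 rose and 5 fell, with Nfkbiz (2.58 ± 0.16) and Irak3 (1.94 ± 0.12) higher. Their median was 0.33 (adjusted p = 2.71e-06, adjusted p = 0.436 with an estimated correlation). Of the unfolded protein and ATF4 genes 14 of 28 rose and 2 fell, with Atf5 (1.66 ± 0.13), Trib3 (1.83 ± 0.18) and asparagine synthetase Asns (1.09 ± 0.12) higher. Their median was 0.32 (adjusted p = 2.88e-05, adjusted p = 0.504 with an estimated correlation, 17 higher and 4 lower adjusted over the list alone). Of the cholesterol synthesis genes 12 of 24 fell, with Cyp51 (-0.45 ± 0.08) and Sqle (-0.40 ± 0.08). Their median was -0.32 (adjusted p = 0.000739, adjusted p = 0.51 with an estimated correlation, 1 higher and 15 lower adjusted over the list alone). In the cell cycle list 1 of 35 rose and 15 fell, with Ccnb2 (-0.72 ± 0.08) lower. Their median was -0.26 (adjusted p = 0.000392, adjusted p = 0.51 with an estimated correlation, 1 higher and 16 lower adjusted over the list alone). In the lysosome list 3 of 36 rose and 10 fell, with the hydrolase Man2b1 (-0.99 ± 0.07) lower. Their median was -0.04 (adjusted p = 0.0386, adjusted p = 0.635 with an estimated correlation, 3 higher and 12 lower adjusted over the list alone). Among matrix genes 8 of 15 rose, with osteopontin Spp1 (2.09 ± 0.12). Their median was 0.63 (adjusted p = 2.18e-05, adjusted p = 0.436 with an estimated correlation). The cystine transporter Slc7a11 (1.93 ± 0.19) and the costimulatory Cd40 (1.96 ± 0.28) rose and Tlr2 (-0.75 ± 0.06) fell in lists without a call.

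The untreated pair stands apart from every other RAW-Blue pair. Its counts differ with a chi-square per degree of freedom of 43.23 (1.95 to 5.78 in the other pairs). The log2 ratio of untreated replicate 2 to replicate 1 follows transcript GC content with a Spearman rho of -0.522 (-0.076 to 0.238 in the other pairs). All 4 comparisons with untreated carry a trend on GC content, with rho -0.273 for SWNT/CpG, -0.392 for CpG, -0.364 for SWNT/LP and -0.307 for CpG+SWNT/LP. Against this control edgeR called 1472 genes higher and 1201 lower of 11514 tested, 449 and 129 by over 2-fold. The count was 5951 without untreated replicate 2, 1211 without SWNT/CpG replicate 1 and 1536 without SWNT/CpG replicate 2. It was 899 with only these groups in the fit.

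With the free oligonucleotide (n = 2, untreated n = 2), 16 of 25 cytokine genes rose in macrophages. Their median was 1.65 (adjusted p = 4.02e-60, adjusted p = 0.079 with an estimated correlation, 21 higher and 0 lower adjusted over the list alone). They include Nos2 (120 ± 15 against 3.83 ± 0.17 CPM, log2 fold change 4.97 ± 0.19, adjusted p = 1.75e-06), Csf3 (25.1 ± 3.8 against 0.412 ± 0.062 CPM, log2 fold change 5.91 ± 0.36, adjusted p = 4.34e-05), Ccl2 (2.62 ± 0.14) and Tnf (1.90 ± 0.08). The serotonin transporter Slc6a4 (4.67 ± 0.16, adjusted p = 8.46e-07) rose, and Cytip (-2.41 ± 0.15), St6gal1 (-2.37 ± 0.12, adjusted p = 5.41e-06) and the endocytosis gene Pacsin1 (-2.92 ± 0.30) fell most. Of the interferon response genes 13 of 43 rose and 1 fell, with Rsad2 (2.08 ± 0.27) and the chemokine Cxcl10 (1.62 ± 0.22) higher. Their median was 0.65 (adjusted p = 3.58e-10, adjusted p = 0.556 with an estimated correlation, 21 higher and 1 lower adjusted over the list alone). Tlr9 (0.44 ± 0.10, adjusted p = 0.0214), the receptor of CpG DNA, was higher. Of the osteoclast genes 3 of 13 rose, with the phosphatase Acp5 (1.57 ± 0.12). Their median was 0.09 (adjusted p = 0.00191, adjusted p = 0.181 with an estimated correlation, 4 higher and 0 lower adjusted over the list alone).

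Among NF-kB feedback genes 10 of 24 rose and 4 fell. Their median was 0.29 (adjusted p = 1.01e-06, adjusted p = 0.448 with an estimated correlation, 12 higher and 6 lower adjusted over the list alone). In the lysosome list 2 of 36 rose and 9 fell. Their median was -0.09 (adjusted p = 0.00472, adjusted p = 0.835 with an estimated correlation, 3 higher and 11 lower adjusted over the list alone). The fold changes follow GC content with rho -0.392, as the untreated pair does. By edgeR 596 genes were higher and 645 lower, 145 and 70 by over 2-fold. The count was 5186 without untreated replicate 2, 2325 without untreated replicate 1, 454 without CpG replicate 1 and 357 without CpG replicate 2. It was 125 with only these groups in the fit.

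With SWNT/LP and no oligonucleotide (n = 2, untreated n = 2), 10 of 25 cytokine genes rose in macrophages. Their median was 0.99 (adjusted p = 4.82e-48, adjusted p = 0.109 with an estimated correlation, 16 higher and 1 lower adjusted over the list alone). They include Nos2 (20.9 ± 0.42 against 3.83 ± 0.17 CPM, log2 fold change 2.45 ± 0.20, adjusted p = 0.00157), Csf3 (4.44 ± 0.27 against 0.412 ± 0.062 CPM, log2 fold change 3.41 ± 0.46, adjusted p = 0.0204), Tnf (0.95 ± 0.08) and the interleukin-1 antagonist Il1rn (1.30 ± 0.10, adjusted p = 0.00157). The chemokine Cxcl2 (69.8 ± 1.5 against 14.3 ± 3.4 CPM, log2 fold change 2.28 ± 0.22, adjusted p = 0.00559), also in the list, rose too. Of the interferon response genes 5 of 43 rose, Rsad2 (2.12 ± 0.27) and Isg15 (1.33 ± 0.19) among them. Their median was 0.79 (adjusted p = 1.61e-33, adjusted p = 0.212 with an estimated correlation, 28 higher and 0 lower adjusted over the list alone). Among SRF and YAP targets 4 of 22 rose, with Fosl1 (0.97 ± 0.14) and Actg2 (1.62 ± 0.21). Their median was 0.19 (adjusted p = 4.49e-07, adjusted p = 0.109 with an estimated correlation, 6 higher and 0 lower adjusted over the list alone). Cytip (-1.0 ± 0.13, adjusted p = 0.014), St6gal1 (-0.73 ± 0.11, adjusted p = 0.0243), Nfam1 (-0.46 ± 0.08) and Tlr2 (-0.38 ± 0.06, adjusted p = 0.0393) fell.

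The fold changes follow GC content with rho -0.364. By edgeR 50 genes were higher and 5 lower, 20 and 0 by over 2-fold. DESeq2 called 151, and edgeR 117 without a filter on low counts, 1 with only these groups in the fit, and 159 with the GC trend removed, a setting added after the data were seen. The count was 4207 without untreated replicate 2, 353 without untreated replicate 1, 3 without SWNT/LP replicate 1, and 2 without SWNT/LP replicate 2.

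In macrophages given both components unjoined (n = 2, untreated n = 2), 18 of 25 cytokine genes rose. Their median was 2.15 (adjusted p = 4.18e-65, adjusted p = 0.0368 with an estimated correlation). Csf3 (76.0 ± 16 against 0.412 ± 0.062 CPM, log2 fold change 7.51 ± 0.34, adjusted p = 3.34e-06), Lcn2 (5.68 ± 0.78), Nos2 (140 ± 32 against 3.83 ± 0.17 CPM, log2 fold change 5.19 ± 0.19, adjusted p = 7.24e-07) and Ccl7 (4.99 ± 0.30) were among the largest rises. Of the osteoclast genes 7 of 13 rose, with the phosphatase Acp5 (1.98 ± 0.12, adjusted p = 9.19e-06), the kinase Src (1.66 ± 0.14) and Jdp2 (1.26 ± 0.07). Their median was 0.33 (adjusted p = 1.78e-06, adjusted p = 0.0368 with an estimated correlation). Cytip (-3.32 ± 0.17), Pacsin1 (-3.29 ± 0.31), the kinase inhibitor Pik3ip1 (-2.94 ± 0.23) and St6gal1 (-2.60 ± 0.13) fell most.

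Of the interferon response genes 16 of 43 rose and 1 fell, with Rsad2 (3.21 ± 0.26) and Cxcl10 (2.40 ± 0.21) higher. Their median was 0.55 (adjusted p = 4.44e-08, adjusted p = 0.514 with an estimated correlation, 18 higher and 1 lower adjusted over the list alone). Among SRF and YAP targets 10 of 22 rose and 3 fell, with Fosl1 (1.99 ± 0.13) higher. Their median was 0.37 (adjusted p = 0.000268, adjusted p = 0.171 with an estimated correlation). Among glycolysis genes 10 of 28 fell. Their median was -0.23 (adjusted p = 3.96e-05, adjusted p = 0.281 with an estimated correlation, 0 higher and 12 lower adjusted over the list alone). The fold changes follow GC content with rho -0.307. By edgeR 1164 genes were higher and 1168 lower, 262 and 111 by over 2-fold, and 443 in all with only these groups in the fit. The count was 5500 without untreated replicate 2, 3630 without untreated replicate 1, 967 without CpG+SWNT/LP replicate 1, and 1020 without CpG+SWNT/LP replicate 2.

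**Figure D4:**
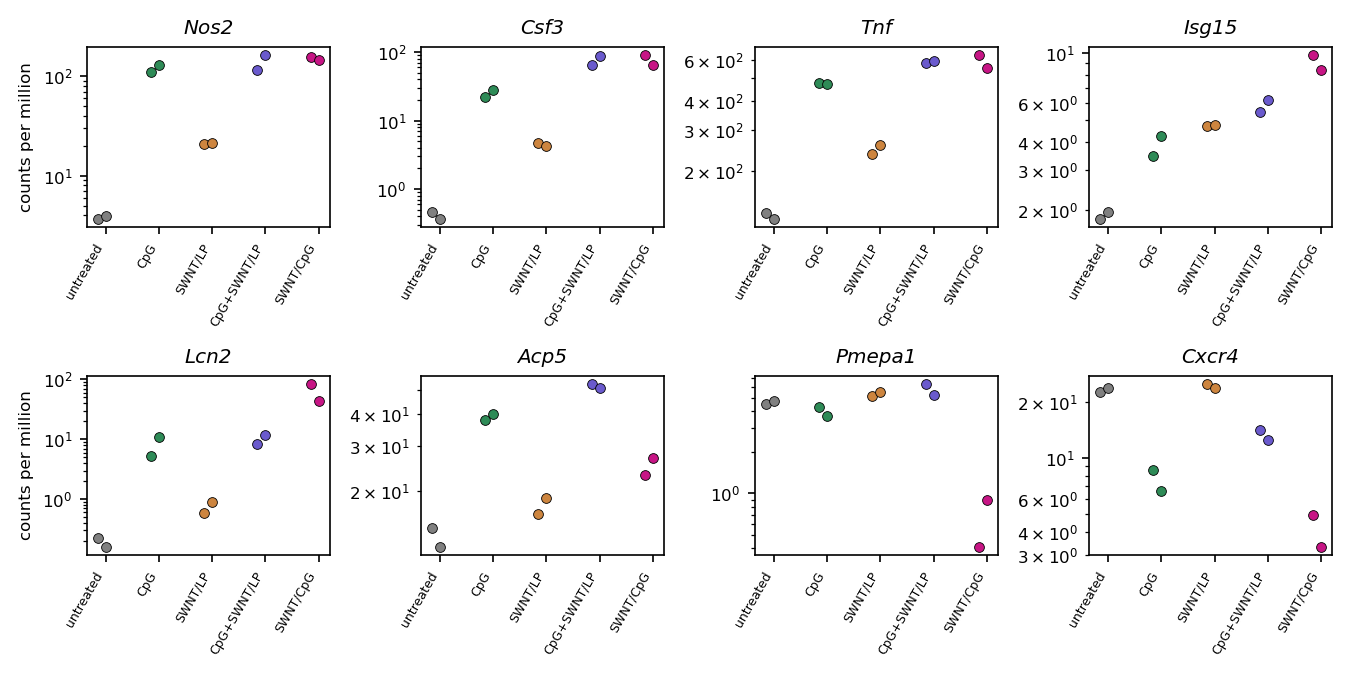
CPM of 8 named genes in each RAW-Blue library, log scale.

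Joining the oligonucleotide to the nanotube, without lipid-PEG, changed 95 genes in macrophages (n = 2 each). Lcn2 (64.5 ± 29 against 10.1 ± 2.5 CPM, log2 fold change 2.66 ± 0.37, adjusted p = 0.026), the secreted Wfdc17 (2.26 ± 0.35), Lix1 (2.19 ± 0.35) and the complement receptor C5ar1 (1.09 ± 0.15, adjusted p = 0.0249) were higher. Pmepa1 (0.652 ± 0.35 against 5.77 ± 0.79 CPM, log2 fold change -3.09 ± 0.28, adjusted p = 0.00722), Cxcr4 (4.11 ± 1.1 against 13.3 ± 1.1 CPM, log2 fold change -1.70 ± 0.18, adjusted p = 0.00917), the maturation marker Cd83 (-1.31 ± 0.17) and Fos (-1.04 ± 0.14) were lower. Of the osteoclast genes 2 of 13 fell, the phosphatase Acp5 (-1.05 ± 0.11, adjusted p = 0.00917) and the transcription factor Nfatc1 (-0.69 ± 0.07, adjusted p = 0.00917). Their median was -0.22 (adjusted p = 1.11e-07, adjusted p = 0.0432 with an estimated correlation, 0 higher and 4 lower adjusted over the list alone). The proton pump subunit Atp6v0d2 (-1.49 ± 0.26) was lower too. Of the interferon response genes 4 of 43 rose, among them the nucleic acid sensor Zbp1 (1.96 ± 0.31), Trim30a (1.01 ± 0.13), Oas1a (0.82 ± 0.14) and Cmpk2 (0.98 ± 0.18). Their median was 0.72 (adjusted p = 3.08e-30, adjusted p = 0.234 with an estimated correlation, 32 higher and 1 lower adjusted over the list alone).

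Antigen presentation genes were called as a list with no member passing over all genes. Their median was 0.30 (adjusted p = 3.14e-06, adjusted p = 0.267 with an estimated correlation, 9 higher and 1 lower adjusted over the list alone). Among SRF and YAP targets 2 of 22 fell, Fos and Egr1 (-0.90 ± 0.12). Their median was -0.20 (adjusted p = 2.84e-05, adjusted p = 0.149 with an estimated correlation, 1 higher and 6 lower adjusted over the list alone). In the lysosome list 2 of 36 fell. Their median was -0.13 (adjusted p = 5.24e-07, adjusted p = 0.442 with an estimated correlation, 0 higher and 7 lower adjusted over the list alone). In the cytokine list 1 of 25 rose. Their median was 0.17 (adjusted p = 0.00271, adjusted p = 0.536 with an estimated correlation, 3 higher and 2 lower adjusted over the list alone). By edgeR 54 genes were higher and 41 lower, 19 and 9 by over 2-fold. DESeq2 called 247, and edgeR 249 without a filter on low counts, 832 with only these groups in the fit, and 369 with the GC trend removed (added after the data were seen). The count was 2 without CpG+SWNT/LP replicate 1, 17 without CpG+SWNT/LP replicate 2, 2 without SWNT/CpG replicate 1, and 8 without SWNT/CpG replicate 2.

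Against the free oligonucleotide (n = 2 each), SWNT/CpG raised Lcn2 (3.00 ± 0.38, adjusted p = 0.0233), Csf3 (1.62 ± 0.19, adjusted p = 0.0182) and Ccl2 (1.25 ± 0.12, adjusted p = 0.0127) in macrophages, and in the cytokine list 8 of 25 rose. Their median was 0.68 (adjusted p = 6.77e-29, adjusted p = 0.186 with an estimated correlation, 16 higher and 0 lower adjusted over the list alone). The interferon genes Isg15 (1.23 ± 0.16, adjusted p = 0.0182), Cmpk2 (1.19 ± 0.19) and Trim30a (0.86 ± 0.13) rose, and in their list 5 of 43 rose. Their median was 0.84 (adjusted p = 2.47e-36, adjusted p = 0.233 with an estimated correlation, 35 higher and 0 lower adjusted over the list alone). Pmepa1 (-2.56 ± 0.29, adjusted p = 0.0127), Ms4a6c (-0.90 ± 0.17), the actin-severing Scin (-0.89 ± 0.14), Fos (-0.79 ± 0.14) and Acp5 (-0.64 ± 0.12) were lower. In the NRF2 list 2 of 24 rose. Their median was 0.16 (adjusted p = 2.49e-05, adjusted p = 0.436 with an estimated correlation, 9 higher and 0 lower adjusted over the list alone). Among phagocytic receptors 2 of 17 rose. Their median was 0.31 (adjusted p = 0.00202, adjusted p = 0.186 with an estimated correlation, 8 higher and 2 lower adjusted over the list alone). Cell cycle genes were called lower as a list with no member passing. Their median was -0.19 (adjusted p = 1.41e-08, adjusted p = 0.36 with an estimated correlation).

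By edgeR 77 genes were higher and 20 lower. DESeq2 called 251, and edgeR 240 without a filter on low counts, 923 with only these groups in the fit, and 339 with the GC trend removed (added after the data were seen). The count was 0 without CpG replicate 1, 0 without CpG replicate 2, 0 without SWNT/CpG replicate 1, and 47 without SWNT/CpG replicate 2.

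With nanotubes in both arms, 18 of 25 cytokine genes of macrophages were higher with the oligonucleotide coating than with lipid-PEG (n = 2 each). Their median was 1.26 (adjusted p = 5.3e-50, adjusted p = 0.12 with an estimated correlation, 21 higher and 1 lower adjusted over the list alone). They include Csf3 (4.12 ± 0.23, adjusted p = 3.75e-05), Lcn2 (6.41 ± 0.52, adjusted p = 0.000199), Nos2 (2.85 ± 0.16) and Tnf (1.26 ± 0.08). Of the interferon response genes 14 of 43 rose, with Cmpk2 (1.31 ± 0.18). Their median was 0.63 (adjusted p = 9.43e-12, adjusted p = 0.327 with an estimated correlation, 23 higher and 0 lower adjusted over the list alone). Among NF-kB feedback genes 11 of 24 rose and 2 fell, with Irak3 (1.92 ± 0.12) higher. Their median was 0.31 (adjusted p = 1.34e-07, adjusted p = 0.327 with an estimated correlation, 13 higher and 4 lower adjusted over the list alone). Tlr9 (0.54 ± 0.10, adjusted p = 0.00803) was higher. Pmepa1 (-2.98 ± 0.28, adjusted p = 0.000211), Cxcr4 (-2.57 ± 0.18), St6gal1 (-2.36 ± 0.13) and Pacsin1 (-2.25 ± 0.30) fell most.

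Among cholesterol synthesis genes 7 of 24 fell. Their median was -0.26 (adjusted p = 5.26e-06, adjusted p = 0.327 with an estimated correlation, 0 higher and 10 lower adjusted over the list alone). In the cell cycle list 1 of 35 rose and 5 fell. Their median was -0.21 (adjusted p = 3.82e-05, adjusted p = 0.327 with an estimated correlation, 1 higher and 6 lower adjusted over the list alone). By edgeR 725 genes were higher and 461 lower, 205 and 70 by over 2-fold, and 3501 in all with only these groups in the fit. The count was 390 without SWNT/LP replicate 1, 430 without SWNT/LP replicate 2, 443 without SWNT/CpG replicate 1, and 629 without SWNT/CpG replicate 2.

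Whether the log2 fold changes of CpG and SWNT/LP add up in macrophages (n = 2 in each of 4 groups) was tested in the same way. Here edgeR called no gene. Nos2 (-2.23 ± 0.25, adjusted p = 0.0681) came closest, and 419 of 11514 genes had unadjusted p under 0.05. The level of Nos2 was 3.83 CPM untreated, 20.9 with SWNT/LP, 120 with CpG and 140 with both. Its departure is thus one of log2 fold changes, and sums of levels in CPM were not tested. DESeq2 called 4, edgeR without a filter on low counts 2, and edgeR with the GC trend removed (added after the data were seen) 1. Cytokines as a list lay below the sum of the 2 log2 fold changes, with no member passing over all genes. Their median was -0.55 (adjusted p = 1.55e-16, adjusted p = 0.491 with an estimated correlation, 0 higher and 3 lower adjusted over the list alone). The interferon response did as well. Their median was -0.82 (adjusted p = 1.01e-31, adjusted p = 0.491 with an estimated correlation, 0 higher and 6 lower adjusted over the list alone). In simulated data with these group sizes 13.4% of genes changed by 1.5-fold and 64.2% of those changed by 2-fold were called, so this test can miss many. With fewer true changes than were simulated it may miss more. The count was 2701 without untreated replicate 2, and 1 without either CpG+SWNT/LP library.

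CpG+SWNT/LP against CpG in macrophages (n = 2 each) was added after the data were seen. Csf3 (1.60 ± 0.19, adjusted p = 0.0391), Il1rn (1.11 ± 0.10, adjusted p = 0.00662), Ccl2 (0.93 ± 0.12, adjusted p = 0.0391), the membrane glycoprotein Pdpn (1.56 ± 0.18) and the protein C receptor Procr (1.18 ± 0.11, adjusted p = 0.00662) were higher, and Tlr2 (-0.43 ± 0.06) lower. Of the cytokine genes 5 of 25 rose. Their median was 0.34 (adjusted p = 2.68e-23, adjusted p = 0.141 with an estimated correlation, 12 higher and 0 lower adjusted over the list alone). Camera called the osteoclast list higher with no member passing over all genes. Their median was 0.17 (adjusted p = 1.22e-07, adjusted p = 0.048 with an estimated correlation, 6 higher and 0 lower adjusted over the list alone). By edgeR 14 genes were higher and 1 lower, and between 0 and 3 in all changed when 1 library was left out. DESeq2 called 47, and edgeR 50 without a filter on low counts, 38 with the GC trend removed and 176 with only these groups in the fit.

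The response to SWNT/CpG differed between the lines for 3392 of 13350 genes (RAW-Blue n = 2 and 2, K-Luc n = 3 and 2). The change was higher in RAW-Blue for 1916 and higher in K-Luc for 1476. The chemokine Ccl7 (4.66 ± 0.33, adjusted p = 1.02e-09), the membrane glycoprotein Pdpn (4.01 ± 0.20, adjusted p = 4.03e-12) and the cysteine-forming enzyme Cth (3.99 ± 0.29, adjusted p = 7.3e-09) had higher changes in RAW-Blue. Pmepa1 (-3.86 ± 0.29, adjusted p = 2.37e-09), Cxcr4 (-3.67 ± 0.38, adjusted p = 2.62e-07), St6gal1 (-3.33 ± 0.19, adjusted p = 2.3e-11) and Lrrc14b (-3.52 ± 0.40) had higher changes in K-Luc. So did Tlr2 (-2.35 ± 0.11, adjusted p = 2.96e-12), which rose in K-Luc and fell in RAW-Blue, while Id1 (3.29 ± 0.23, adjusted p = 1.59e-09) fell in K-Luc and rose in RAW-Blue.

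In the interferon response 25 of 45 had the higher change in RAW-Blue and 1 in K-Luc, with Isg15 (2.71 ± 0.21) and Oasl1 (3.13 ± 0.31) among the higher in RAW-Blue. Their median was 1.34 (adjusted p = 4.28e-13, adjusted p = 0.355 with an estimated correlation, 31 higher and 1 lower adjusted over the list alone). In the cytokine list 9 of 28 had the higher change in RAW-Blue and 1 in K-Luc. Their median was 2.32 (adjusted p = 7.2e-05, adjusted p = 0.355 with an estimated correlation). Only 14 cytokine genes passed the filter in K-Luc, so this median rests partly on genes with too few K-Luc counts to test there. In the cell cycle list 31 of 35 had the higher change in RAW-Blue and 0 in K-Luc. Their median was 0.65 (adjusted p = 3.85e-16, adjusted p = 0.345 with an estimated correlation, 33 higher and 0 lower adjusted over the list alone). Among NRF2 genes 12 of 26 had the higher change in RAW-Blue and 0 in K-Luc, with Slc7a11 (1.87 ± 0.21). Their median was 0.28 (adjusted p = 0.0003, adjusted p = 0.394 with an estimated correlation, 13 higher and 0 lower adjusted over the list alone). Among lysosomal genes 2 of 36 had the higher change in RAW-Blue and 22 in K-Luc, with Man2b1 (-1.37 ± 0.11) higher in K-Luc. Their median was -0.53 (adjusted p = 8.33e-11, adjusted p = 0.371 with an estimated correlation, 2 higher and 24 lower adjusted over the list alone). Among cholesterol synthesis genes 1 of 24 had the higher change in RAW-Blue and 13 in K-Luc. Their median was -0.43 (adjusted p = 1.86e-07, adjusted p = 0.355 with an estimated correlation, 1 higher and 15 lower adjusted over the list alone). Incubation was 17 to 19 h for K-Luc and 47 to 50 h for RAW-Blue, so line and time cannot be separated. With TMM scaling 56.5% of the called genes had the higher change in RAW-Blue and with DESeq2 size factors 44.6%, so the split by direction depends on scaling. The count was 4878 without RAW-Blue untreated replicate 2 and 2019 without K-Luc untreated replicate 2.

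Calls were compared between the lines, which share no control. The numbers set beside each count are those under independent calls in the 2 lines. The Fisher test treats genes as independent, so its p is too small where genes change together. It also leaves out that well-counted genes are easier to call in both lines. Of 10576 genes tested in both, 374 rose with SWNT/CpG in both lines where 254.8 would (odds ratio 1.81, Fisher p = 1.2e-17). Another 296 fell in both where 254.1 would. In opposite directions, 288 rose in K-Luc and fell in RAW-Blue where 228.1 would, and 204 fell in K-Luc and rose in RAW-Blue where 283.8 would (odds ratio 0.632, Fisher p = 3.93e-09). For the free oligonucleotide 210 genes rose in K-Luc and fell in RAW-Blue where 90.5 would (odds ratio 3.41, Fisher p = 3.02e-36), and 136 fell in K-Luc and rose in RAW-Blue where 100.2 would. In the same direction, 72 rose in both where 78.5 would (Fisher p = 0.449), and 54 fell in both where 115.5 would. For CpG+SWNT/LP 151 rose in both where 145.9 would and 121 fell in both where 209 would, while 265 rose in K-Luc and fell in RAW-Blue where 151.7 would and 239 did the opposite where 201 would. Fold changes for the oligonucleotide follow GC content with rho 0.145 in K-Luc and -0.392 in RAW-Blue, which by itself would favour opposite calls. The same holds for SWNT/CpG (0.147 and -0.273) and for CpG+SWNT/LP (0.203 and -0.307). Tlr9 had 4 counts over the 14 K-Luc libraries, too few to test, and 3330 over the 10 RAW-Blue libraries (17.8 CPM). Its trafficking partner Unc93b1 stood at 6.08 CPM in K-Luc and 270 in RAW-Blue, and the adaptor Myd88 at 24.9 and 92.4. Tnf had 1 count in all K-Luc libraries.

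**Figure D5:**
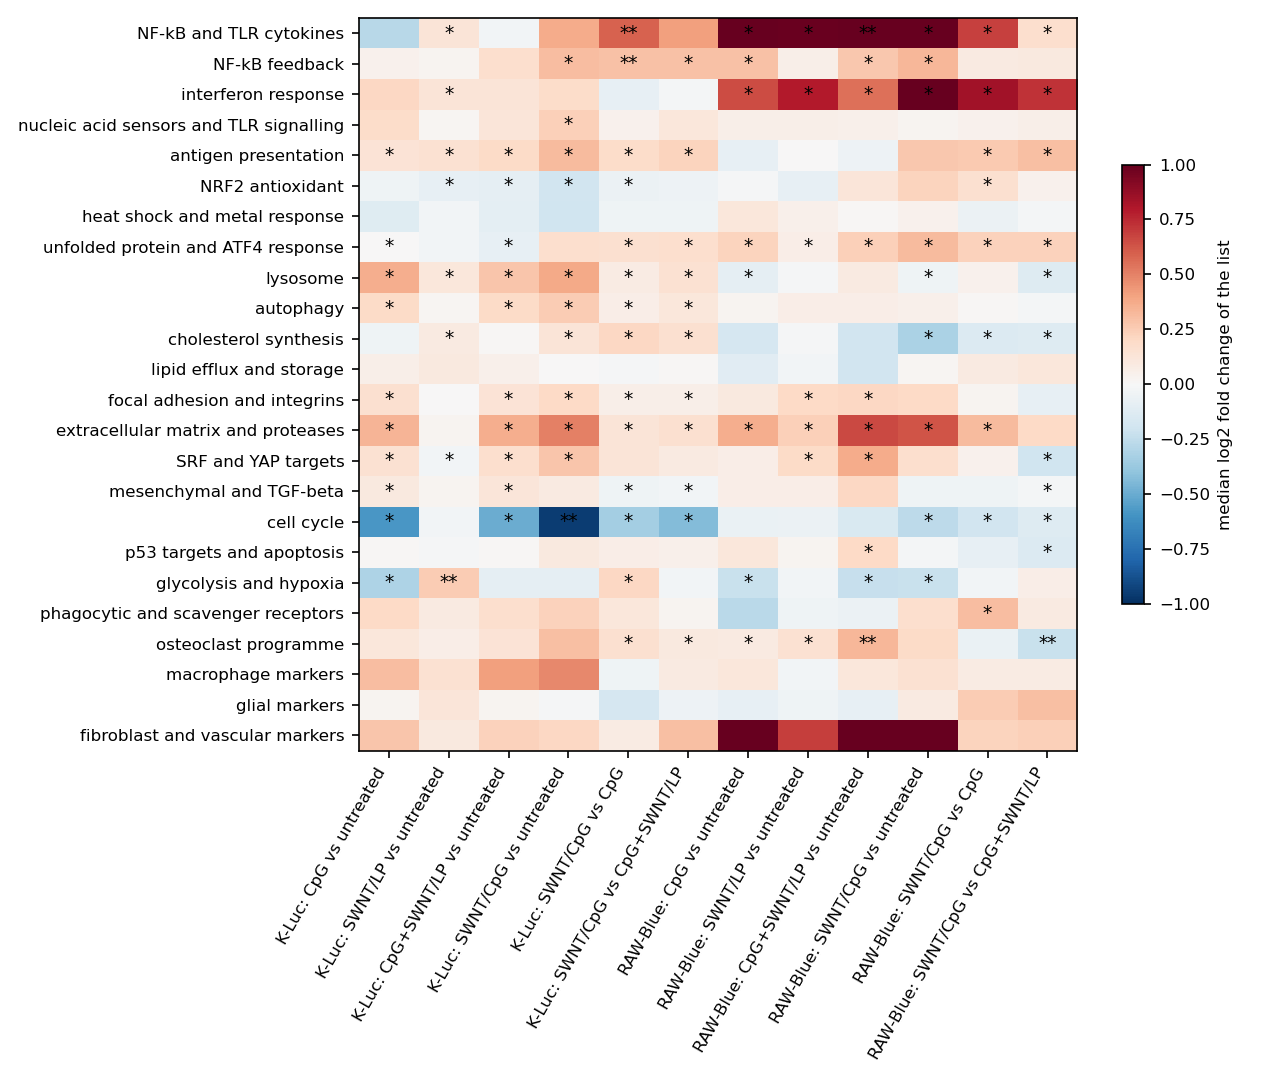
Median log2 fold change of 24 fixed gene lists in 12 comparisons. One asterisk marks a camera call with the preset correlation, and 2 asterisks a call kept with an estimated correlation.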

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

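The tests of sequencing run and of NRF2 activity, and the average over CpG that the last pattern uses, were chosen only after the results were seen. A tested difference between the cell lines in the response to SWNT/CpG marks 3392 genes for a closer look, and among those with the largest differences 8 named genes with more than 3 counts in each group: Ccl7 (difference in log2 fold change, RAW-Blue minus K-Luc, 4.66), Hecw2 (4.23), Pdpn (4.01), Cth (3.99), Pmepa1 (-3.86), Cxcr4 (-3.67), Lrrc14b (-3.52) and St6gal1 (-3.33). No biological explanation of these differences was tested, since line and incubation time change together. Among K-Luc groups of 3, other splits of the 6 libraries gave at most 0 called genes against 2194 for SWNT/CpG against CpG+SWNT/LP, 1847 against CpG and 5173 against SWNT/LP. In each, 1 of 10 splits, the real one, reached its count, and 10 splits cannot give a share under 0.05. Every other split holds both treatments in each arm, so a treatment difference adds to its spread. The 0 calls are thus no measure of what chance alone would give.

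In RAW-Blue macrophages 10 of 25 cytokine genes rose with nanotubes that carried no oligonucleotide (list adjusted p = 4.82e-48, adjusted p = 0.109 with an estimated correlation). The 55 genes called in this comparison became 3 without SWNT/LP replicate 1 and 2 without replicate 2. A difference between the untreated libraries does not account for it, since the list median was 1.04 (bootstrap interval over genes 0.46 to 1.40) against either untreated library alone. Neither does a trend on GC content and transcript length, since the median was 0.97 (0.40 to 1.38) with that trend removed and 0.98 before. What stays open is a response to the nanotubes, to the lipid-PEG, or to a contaminant such as endotoxin, none of which the groups separate.

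In K-Luc cells Id1, Id2 and Id3 were lower and Pmepa1 higher with SWNT/CpG than with CpG+SWNT/LP. Sequencing run is excluded as the cause, since each group has 1 of its 3 libraries in run 1. In run 2 alone the weakest of the 4 genes, which were chosen from these data, was 10.35 standard errors from 0. Lower BMP signalling stays open: 5 other BMP readouts had a median of -0.44 and were lower as a set by fry, with Id4 (-0.71), Smad6 (-0.44) and Smad9 (-0.62) passing and Bambi (-0.05) and Hey1 (-0.39) not. Higher TGF-beta signalling stays open as well: 5 other readouts had a median of 0.62 and were higher as a set by fry, with Ldlrad4 (0.69), Ltbp2 (0.69), Bhlhe40 (0.62) and Tgif1 (0.44) passing and Tgfbi (0.09) not. The 2 groups also differ in lipid-PEG, so neither readout tells the joining from its absence.

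Aldh3a1, Cyp1b1 and Nqo1 were lower in K-Luc cells with nanotubes of either coating. Averaged over CpG absent and present, SWNT/LP changed them by -1.32 ± 0.17, -1.36 ± 0.15 and -0.56 ± 0.06. In the planned comparison of SWNT/LP with untreated, Nqo1 was called lower, but Aldh3a1 and Cyp1b1 were not. Sequencing run is excluded, since in run 2 alone the weakest of the 3 was 7.86 standard errors below 0 for SWNT/CpG against CpG and 6.79 for the SWNT/LP average. Run 2 holds a single untreated library, so in that average its spread is assumed from the other groups. The other 25 NRF2 genes had a median of -0.07 (-0.11 to -0.06), which argues against a fall this large across NRF2 genes. It does not exclude lower NRF2 activity as the cause, since its targets need not fall alike. That cause stays open, since the other NRF2 genes were lower as a set by fry. Nfe2l2, which encodes NRF2, was itself lower (-0.26 ± 0.03, adjusted p = 0.000722). Lower aryl hydrocarbon receptor activity stays open: 3 other readouts had a median of -0.22 and were lower as a set by fry, though only Tiparp passed (adjusted p = 0.00586) and Cyp1a1 was near the floor.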

How the results depend on the processing

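Removal of the GC trend in RAW-Blue was added after the data were seen, and so were the 2 comparisons of CpG+SWNT/LP with CpG. Every other alternative was planned. Over 32 settings, each run where it applies to a comparison, no named gene reversed. Of 264 gene values, 189 lost no call in any setting run for them. Some of the 264 had no call in the main fit and so had none to lose. Among the 264 values DESeq2 ended 0 calls, its size factors in edgeR 1 and no filter 6. Run 2 alone ended 13 among 154 values and no run term 4. Only the compared groups in the fit ended 33 among 250, and leaving out 1 library 181 among 1328. Over the 17 planned comparisons and all 25 lists there were 158 list calls. Of these, 8 were kept with an estimated correlation and 119 with fry, which also called 61 more. The added comparisons are not in these counts.

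The main count comes first here and the changed count after it. DESeq2 moved SWNT/LP against untreated from 16 to 33 in K-Luc and from 55 to 151 in RAW-Blue, and in RAW-Blue SWNT/CpG against CpG+SWNT/LP from 95 to 247, against CpG from 97 to 251, and the interaction from 0 to 4. Without the filter on low counts these became 27, 117, 249, 240 and 2. With the GC trend removed the last 4 became 159, 369, 339 and 1. In run 2 alone the K-Luc counts were 5 for SWNT/LP against untreated, 2043 (from 4213) for CpG+SWNT/LP against untreated and 1177 (from 2194) for SWNT/CpG against CpG+SWNT/LP, with fewer libraries in the fit. With only the compared groups in the fit, K-Luc gave 2543 (from 4498) for CpG against untreated, 2 for SWNT/LP against untreated and 3695 for SWNT/CpG against CpG+SWNT/LP. RAW-Blue gave 899 (from 2673) for SWNT/CpG against untreated, 125 (from 1241) for CpG, 1 for SWNT/LP and 443 (from 2332) for CpG+SWNT/LP, and for SWNT/CpG 832 against CpG+SWNT/LP, 923 against CpG and 3501 (from 1186) against SWNT/LP. That setting estimates spread from as few as 4 libraries. Beyond the number of libraries in a fit, the cause was not tested.

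Replicate number as a block moved K-Luc SWNT/LP against untreated to 61, SWNT/CpG against CpG+SWNT/LP to 4009, SWNT/CpG against CpG to 3610 (from 1847), the interaction to 2 in K-Luc and 1 in RAW-Blue, and the added CpG+SWNT/LP against CpG to 201 (from 33) in K-Luc and 2 (from 15) in RAW-Blue. Among the 264 gene values, 10 calls were lost with the block. The labels do not say that equal numbers mark libraries handled together. After group means, 20 of 26 equally numbered K-Luc pairs and 4 of 20 RAW-Blue pairs correlated above 0.1. Run 1 holds only libraries numbered 1, so removing run (6 of 26 left) also removes part of any pairing. Within run 2, 5 of 13 K-Luc pairs did, and all 10 libraries correlated best with their own number, as did 12 of all 14. In RAW-Blue all 10 libraries did as well, with a median correlation of 0.02 between equally numbered pairs. With 2 libraries per group these deviations mirror each other, so each RAW-Blue correlation recurs under both numbers. The RAW-Blue counts thus overstate the separate pairs and libraries, and no chance level was computed. In K-Luc CpG and SWNT/LP, all run 2, chi-square per degree of freedom was 8.94 to 14.48 for pairs with replicate 1 and 3.36 and 3.44 for the others. Replicate 1 had the highest value on the 1st principal component in every K-Luc group. It stood at 16.03 against 5.33 and 5.46 in CpG, and at -12.89 against -28.26 and -26.3 in SWNT/LP. Comparisons of CpG or SWNT/LP with the other groups may thus hold a difference of replicate 1. The data thus hint at a shared source by number, more strongly in K-Luc. Neither the labels nor every pair show it, so the numbers are not treated as pairs.

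Leaving out 1 library gave these lowest and highest counts, where a group left with 1 library is assumed to vary like the others. In K-Luc, SWNT/CpG against untreated gave 2770 to 4629, CpG 1531 to 4343, SWNT/LP 0 to 22 and CpG+SWNT/LP 1454 to 3550, SWNT/CpG gave 1423 to 1603 against CpG+SWNT/LP, 1091 to 1861 against CpG and 3950 to 5883 against SWNT/LP, and the interaction 0 to 0. In RAW-Blue the same order gave 1211 to 5951, 357 to 5186, 2 to 4207, 967 to 5500, 2 to 17, 0 to 47, 390 to 629 and 0 to 2701. Between the lines the range was 2019 to 4878. The RAW-Blue upper ends against untreated and for the interaction all lack untreated replicate 2.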

Other observations

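The average effect of SWNT/LP over CpG absent and present in K-Luc cells was added after the data were seen, and its genes were chosen after their values were seen. It called 29 genes higher and 41 lower. Among the higher were Pdk1 at 0.49, Bnip3 at 0.47, Pfkl at 0.44 and Ldha at 0.31, and the iron-binding Lcn2 at 3.19 ± 0.47. Lcn2 was not among the largest rises named by rule in any K-Luc comparison. Its K-Luc level is not given here, so its rise may rest on low counts. The pentraxin Ptx3 was lower at -0.97 and the alcohol dehydrogenase Adh7 at -0.49, and the uncharacterised 1190005I06Rik had the largest fall, -1.58.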
